A study of Mus musculus with 6 samples.

How the data were processed

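Total RNA from 6 mouse hearts was hybridised to Affymetrix whole-transcript arrays, 1 array per heart, in groups of 3 (ETX) and 3 (PBS); the groups and replicate numbers come from the labels, which call the hearts biological replicates. The deposited log2 values are the authors' own: they were made with Affymetrix Expression Console and the RMA method, per the submitters' processing notes, which name no version. RMA corrects the background, normalizes quantiles between arrays and summarises probes by median polish, which pulls the arrays to a common distribution and compresses differences of dim transcripts. The annotation, any filter and whether other arrays were normalized together with these are not given in the sources used here. The lowest values lay between 1.01 and 1.24 and the highest between 13.5 and 13.6 on the log2 scale. There is no detection call in the values used here, so a level near the low end gives no reliable fold.

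The value table held 35556 transcript clusters. A platform annotation table named 23410 of them, 21789 with 1 gene symbol and 1621 with several; 12146 clusters had no gene in that table. Gene identifiers of 21698 clusters with 1 symbol were found in a mouse RefSeq gene table, and 0 symbols changed by it. The genome build of the array annotation is not named, so no coordinates are given. Genes were taken from clusters with exactly 1 symbol, 19938 genes in all. For the 999 genes with more clusters the brightest over all 6 arrays was used; all clusters of a called gene shared its sign in 26 of the 26 called genes with over 1 cluster. Genes whose mean over all arrays lay under the lower quartile of gene means (3.45 on the log2 scale) were left out, which kept 14953.

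ETX and PBS were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Beside it stands a descriptive count of genes changed at least 1.5-fold with an unadjusted p under 0.05. Values are given as mean ± SD of 3 hearts, and fold changes are 2 to the power of the difference of log2 means. The 34 gene lists (metabolism, cell cycle, stress, immune, cardiomyocyte and cell type lists), the test of each result, the alternatives and the rule for naming genes were fixed before the data were examined. Of 688 list entries 634 were measured on clusters with 1 gene, 17 only on clusters with several genes and 37 were not found; Cpt1b and Cdkn1a lay only on clusters with several genes and Ccnb1 was not found by its symbol, so these are not reported. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 34 lists, with an estimated correlation, ranks and fry as alternatives. The test, mean and median of a list differed in sign for 6 lists, none of them called: lipid synthesis and storage, cholesterol synthesis, ketone and branched-chain amino acid use, lymphocyte and thymus, skeletal muscle, and circadian clock.

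The genes named are the 12 largest rises and 12 largest falls past the threshold without overlap between groups (predicted genes without an established name, olfactory and vomeronasal receptors and small RNA genes were counted and not named), up to 4 members of each list with the smallest p, and a fixed set of metabolic, cell cycle and cardiac genes. Myl7 and the genes named only in the closing observations were chosen after their values were seen. A list score is the mean log2 value of its members in a heart, and its 95% interval comes from a linear model over the 6 hearts.

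The functions were tested on simulated data for ETX against PBS, with normal errors of the moderated size around the means of the 14953 genes. Of 100 genes changed 1.5-fold 92% were recovered with the right sign, and of 100 changed 2-fold 99%; 9 other genes were called, and 0 when nothing was changed. The 2 simulated lists shifted by 0.3 were recovered, and 0 of 18 others were called. The simulation assumes independent hearts without structure between them. It also draws each gene independently, so it cannot show how often the list test calls lists whose members are correlated. In the real data the estimated correlation was 0.60 for the mitosis list and 0.54 for the interferon list.

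The alternatives were other filters on dim genes, the eBayes options, array weights, other normalizations, the mean of clusters, all transcript clusters, an unmoderated test, other thresholds, other set tests and each heart left out in turn. Added after seeing the data were fits without the hearts with lung or with high atrial transcripts (which leave 1 heart in a group, assumed to vary like the others), fits with the sex of the animal (read from Xist), the lung-marker score or the atrial-marker score as a covariate, and 8 further gene lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.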

Results

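Gene expression was measured on Affymetrix whole-transcript arrays in hearts of C57BL/6J mice at postnatal day 14, after 1 week of treatment with ETX or with its vehicle, phosphate-buffered saline (PBS). The labels do not spell out ETX; the gene lists were drawn up with a treatment acting on fatty acid oxidation in mind. Each group held 3 hearts described as biological replicates (PBS replicates 3, 9 and 12 and ETX replicates 6, 7 and 10), with 1 array per heart. This number of arrays limits the precision. The deposited values are log2 signals, and the 6 arrays had medians between 4.43 and 4.51. Arrays correlated at 0.993 to 0.994 within ETX, 0.989 to 0.992 within PBS and 0.985 to 0.989 between the groups, across transcript clusters, which are not independent replicates. No 2 arrays held identical columns. The comparison asks which transcripts differed between ETX and PBS hearts at this age.

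The ETX hearts held more Acta1 (skeletal muscle alpha-actin, abundant in the foetal heart) and more Ptgds (a prostaglandin D2 synthase), and less of the MHC class II transcripts Cd74, H2-Aa and H2-Ab1, which serve antigen presentation. Acta1 rose 3.47-fold, from 8.22 ± 0.21 to 10.02 ± 0.37 (SD, n = 3 per group, limma adjusted p = 0.00617). Ptgds rose 3.54-fold, from 5.96 ± 0.25 to 7.79 ± 0.70 (limma adjusted p = 0.0266). Cd74 fell from 7.56 ± 0.63 to 5.27 ± 0.21 and was 4.88-fold lower (limma adjusted p = 0.00857). H2-Aa was 4.19-fold lower with 6.54 ± 0.21 in PBS and 4.47 ± 0.13 in ETX (limma adjusted p = 0.000555). Lung transcripts were high in PBS replicates 3 and 9, and in PBS replicate 12, without them, Cd74 was at 7.11 and H2-Aa at 6.42. Of 14953 genes tested, 533 passed an adjusted p of 0.05 in limma, 170 higher and 363 lower in ETX. The ETX and PBS values of all 533 did not overlap. Each called gene that fell, Cd74 and H2-Aa included, therefore lay above ETX in PBS replicate 12. Without overlap were 4144 tested genes, or 27.7%, where chance gives 10%. The changes were mostly modest: the median fold of the called genes was 1.38 for rises and 1.39 for falls, and 50 rising and 103 falling genes changed at least 1.5-fold. At an unadjusted p under 0.05 and at least 1.5-fold, 240 genes were counted, 82 higher and 158 lower. With each array centred on its median, 78.6% of the called genes were lower in ETX, and with a further quantile normalization 58.3%, against 68.1% as deposited.

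The remaining large rises were Fstl4 (2.89-fold), Bex1 (3.10 ± 0.19 in PBS, 4.61 ± 0.23 in ETX), the cytokine Mif (2.15-fold), the ceramidase Acer2 (2.12-fold), and Adam22 (1.93-fold). Further rises were those of the tropomyosin Tpm2 (1.92-fold), Clca3a1 (3.20 ± 0.17 in PBS, 4.14 ± 0.19 in ETX), Ctla2a (1.92-fold), the ketone body enzyme Bdh1 (1.91-fold) and Dio2, which activates thyroid hormone (1.85-fold). The remaining large falls were the carboxylesterase Ces1d (3.45-fold lower), the orphan nuclear receptor Nr4a1 (3.44-fold), H2-Ab1 (2.85-fold), and complement component C7 (2.64-fold). Further falls were those of the membrane peptidase Mme (2.52-fold), Arhgap20 (2.51-fold), Cyp1a1 (4.65 ± 0.53 in PBS, 3.37 ± 0.12 in ETX), the phospholipase Pla2g5 (2.35-fold), the insulin receptor substrate Irs2 (2.35-fold) and Akap5 (2.30-fold). No fold is given for Bex1, Clca3a1 and Cyp1a1, whose mean in 1 group lies under the quartile of 3.45 below which genes count as dim. The limma adjusted p of these genes lay between 0.000555 and 0.0486. With each heart left out in turn, Acta1, Fstl4, Bex1, Mif, Acer2, Adam22, Tpm2, Clca3a1, Dio2, Cd74, H2-Aa, H2-Ab1, Mme, Arhgap20, Pla2g5 and Irs2 passed in all 6 fits. Ptgds, Ctla2a, Bdh1, Ces1d, Nr4a1, C7, Cyp1a1 and Akap5 lost the call in at least 3 of them, with the largest limma adjusted p between 0.0717 for Ces1d and 0.133 for Akap5. With the lung-marker score in the fit, Adam22, Dio2 and Irs2 did not pass (limma adjusted p = 0.0637, 0.0583 and 0.0712). Ptgds, Ctla2a, Bdh1, Ces1d, Nr4a1, C7 and Akap5 did not pass there either (up to 0.198), and the other genes named here did. C7 shrank from -1.40 to -0.85 and Akap5 from -1.20 to -0.71, whereas Ces1d and Nr4a1 moved from -1.78 to -1.89 and -2.13. The covariate takes a degree of freedom.

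**Figure D1:**
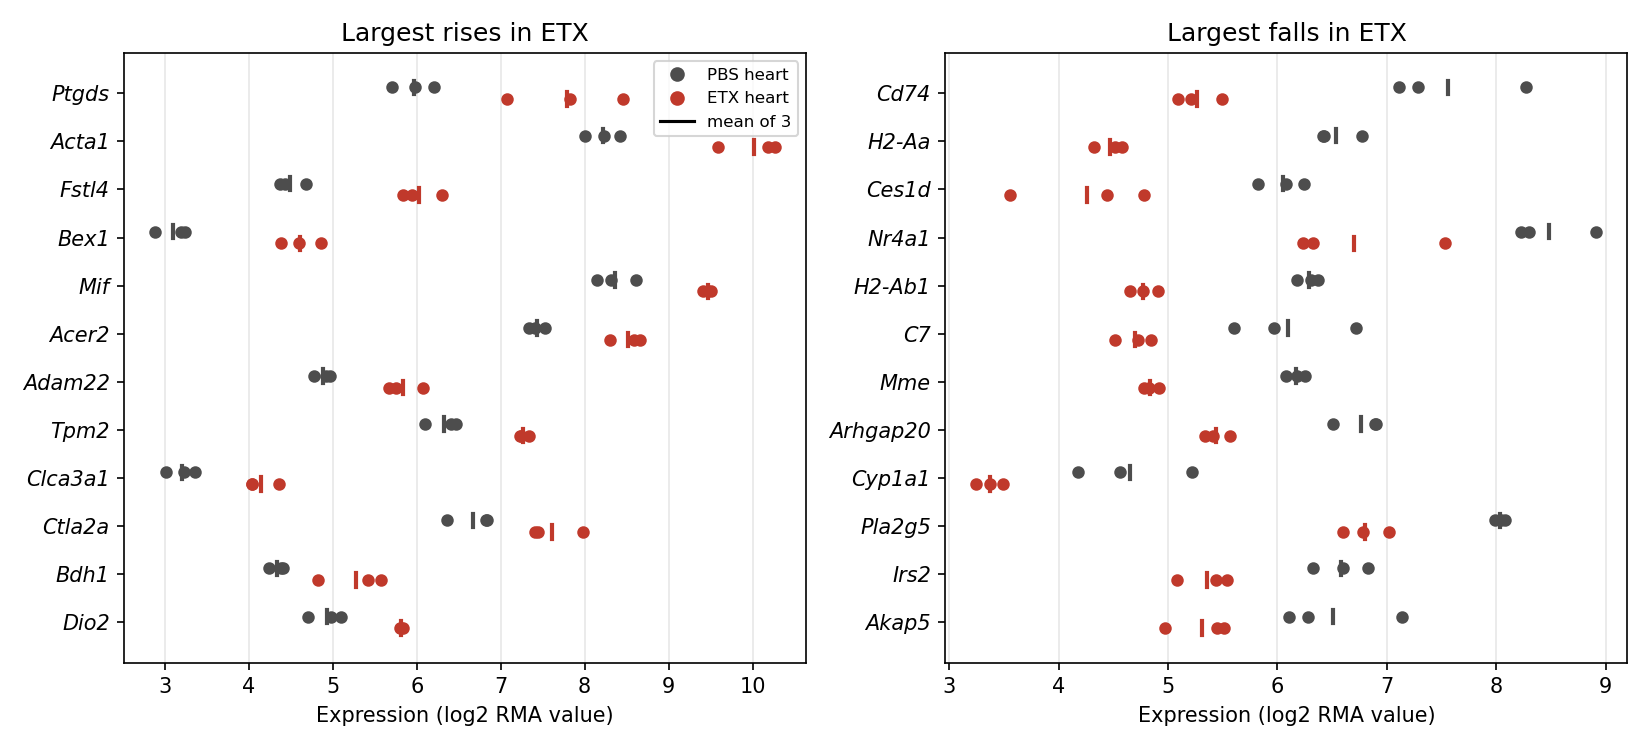
Log2 RMA value (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, with a point for each heart and a bar for the mean of 3 hearts. The PBS and ETX points of each gene do not overlap; Acta1 has a mean of 8.22 in PBS and 10.02 in ETX, and H2-Aa 6.54 and 4.47.

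Among the metabolic lists, glycolysis and glucose uptake was higher in ETX (camera adjusted p = 0.00561, median log2 difference 0.08, 17 of 21 members above 0, adjusted p = 0.465 with an estimated correlation). No member passed over all genes tested, and 4 rose when adjusted over the list alone. Its leading members, all higher in the 3 ETX hearts than in any PBS heart, were the glucose transporter Slc2a1 (6.44 ± 0.17 in PBS, 6.83 ± 0.07 in ETX, limma adjusted p = 0.0675) and the glycolytic enzymes Pgam2 (log2 difference 0.33, adjusted p = 0.0512), Pfkl (0.33, 0.0518) and Pgk1 (0.33, 0.056). Without PBS replicate 9 Slc2a1 passed (limma adjusted p = 0.0361). The list score, the mean log2 value of its members per heart, was 0.10 higher in ETX (95% interval 0.07 to 0.14). The median of the list was 0.055 with arrays centred on their median and 0.14 with the lung-marker score in the fit, and the list passed in both. Mitochondrial fatty acid oxidation did not pass (camera adjusted p = 0.194, median log2 difference -0.07), and 0 of its 19 members were called over all genes or adjusted over the list alone. The score of this list differed by -0.075 (95% interval -0.15 to -0.00088). Echs1 (-0.26, limma adjusted p = 0.0948), Cpt2 (-0.23, 0.106), Acads (-0.33, 0.139) and Acadm (-0.22, 0.146) were its members with the smallest p, and Cpt1a differed by -0.07 (adjusted p = 0.657). The list of PPAR-alpha target genes did not pass as a whole (camera adjusted p = 0.245, median -0.05), but 2 of its 18 members fell over all genes and adjusted over the list alone, the enoyl-CoA isomerase Ech1 (1.35-fold, limma adjusted p = 0.0277) and the lipid droplet protein Plin2 (1.26-fold, 0.0418). Pdk4 (-0.27, 0.16) and Angptl4 (-0.43, 0.158) did not pass, nor did Ucp3 (0.18, 0.336) and Acot1 (0.05, 0.797). With 1 heart left out the differences of Acads, Cpt1a, Ucp3 and Acot1 moved by more than 1.5 times, and none of them passed. The median of the PPAR-alpha list ran from -0.057 to -0.019 in these fits. Over all hearts its score differed by -0.097 (95% interval -0.18 to -0.011). The score intervals of these lists are not adjusted for the number of lists. Ech1 and Plin2 lost the call in at least 5 of the 6 fits without 1 heart, with a limma adjusted p of up to 0.103 and 0.147.

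In the list of pyruvate dehydrogenase and the TCA cycle, Pdk1, a kinase that inhibits pyruvate dehydrogenase, rose from 8.15 ± 0.05 to 8.52 ± 0.02 (limma adjusted p = 0.0256) and the fumarase Fh1 was 1.23-fold lower (0.0411), while the list did not pass (camera adjusted p = 0.764, 3 higher and 2 lower adjusted over the list alone). The 43 tested oxidative phosphorylation subunits had a median of 0.01 (camera adjusted p = 0.571), with 0 called over all genes in limma or adjusted over the list alone. Among the lipid synthesis and storage genes the desaturase Scd2 rose 1.58-fold (limma adjusted p = 0.00792) and Cidea 1.39-fold (0.0266), and Plin2 fell (list camera adjusted p = 0.683, 3 higher and 1 lower adjusted over the list alone). Of the cholesterol synthesis genes Stard4 and Sc5d fell (limma adjusted p = 0.0251 and 0.0385, list camera adjusted p = 0.764, 2 lower adjusted over the list alone). Bdh1 was the called member of the ketone and branched-chain amino acid list (camera adjusted p = 0.764, 2 higher and 3 lower adjusted over the list alone). In the list of hypoxia target genes, Pdk1 and Ankrd37 (1.57-fold, limma adjusted p = 0.0314) rose, and the list did not pass (camera adjusted p = 0.203, 5 higher adjusted over the list alone), but did without PBS replicate 12 (0.042). Without 1 heart, Scd2 passed in all 6 fits, whereas Pdk1, Fh1, Cidea, Plin2, Stard4, Sc5d, Bdh1 and Ankrd37 each lost the call in at least 4.

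Cell cycle genes were higher in ETX as lists. Of the mitosis (G2/M) genes 26 of 27 lay above 0 (camera adjusted p = 1.9e-08, median log2 difference 0.40, adjusted p = 0.557 with an estimated correlation). Over all genes 1 member passed, the mitotic transcription factor Foxm1 (1.36-fold, limma adjusted p = 0.0322), and adjusted over the list alone 6 rose and 1 fell. Of the DNA replication (G1/S) genes 25 of 27 lay above 0 (camera adjusted p = 1.3e-06, median 0.21, adjusted p = 0.557 with an estimated correlation), and thymidine kinase Tk1 was called over all genes and adjusted over the list alone (1.32-fold, limma adjusted p = 0.0318). The ETX hearts differed among themselves. Top2a was at 5.21 in ETX replicate 6, 6.10 in ETX replicate 7 and 5.83 in ETX replicate 10, against 4.81 to 5.11 in PBS. It did not pass (limma adjusted p = 0.104) but did without ETX replicate 6 (0.0314). Mki67 was at 5.87 in ETX replicate 6, inside the PBS range of 5.80 to 6.29, with a group difference of 0.39 (limma adjusted p = 0.357), and Cdk1 differed by 0.27 (0.287). With 1 heart left out these ran from 0.18 (without ETX replicate 7) to 0.65 (without ETX replicate 6) for Mki67 and from 0.17 to 0.43 for Cdk1 in the same fits, and neither passed. The mean score of the mitosis list was 0.37 higher in ETX, with a 95% interval of -0.09 to 0.82. That of the replication list was 0.21 higher (-0.02 to 0.44). Of the cell cycle inhibitors, Cdkn1c (1.39-fold, limma adjusted p = 0.0158) and Gadd45b (1.41-fold, 0.0399) fell, and the list did not pass (camera adjusted p = 0.0734, 5 lower adjusted over the list alone), but did without ETX replicate 7 (0.0422) or ETX replicate 10 (0.0268). Cdkn1c lost the call without ETX replicate 6 or 7 (limma adjusted p up to 0.0672). Foxm1, Tk1 and Gadd45b lost it in at least 5 of the 6 fits without 1 heart, and the mitosis and replication lists passed in all 6. Without ETX replicate 7 the median of the mitosis list was 0.25.

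**Figure D2:**
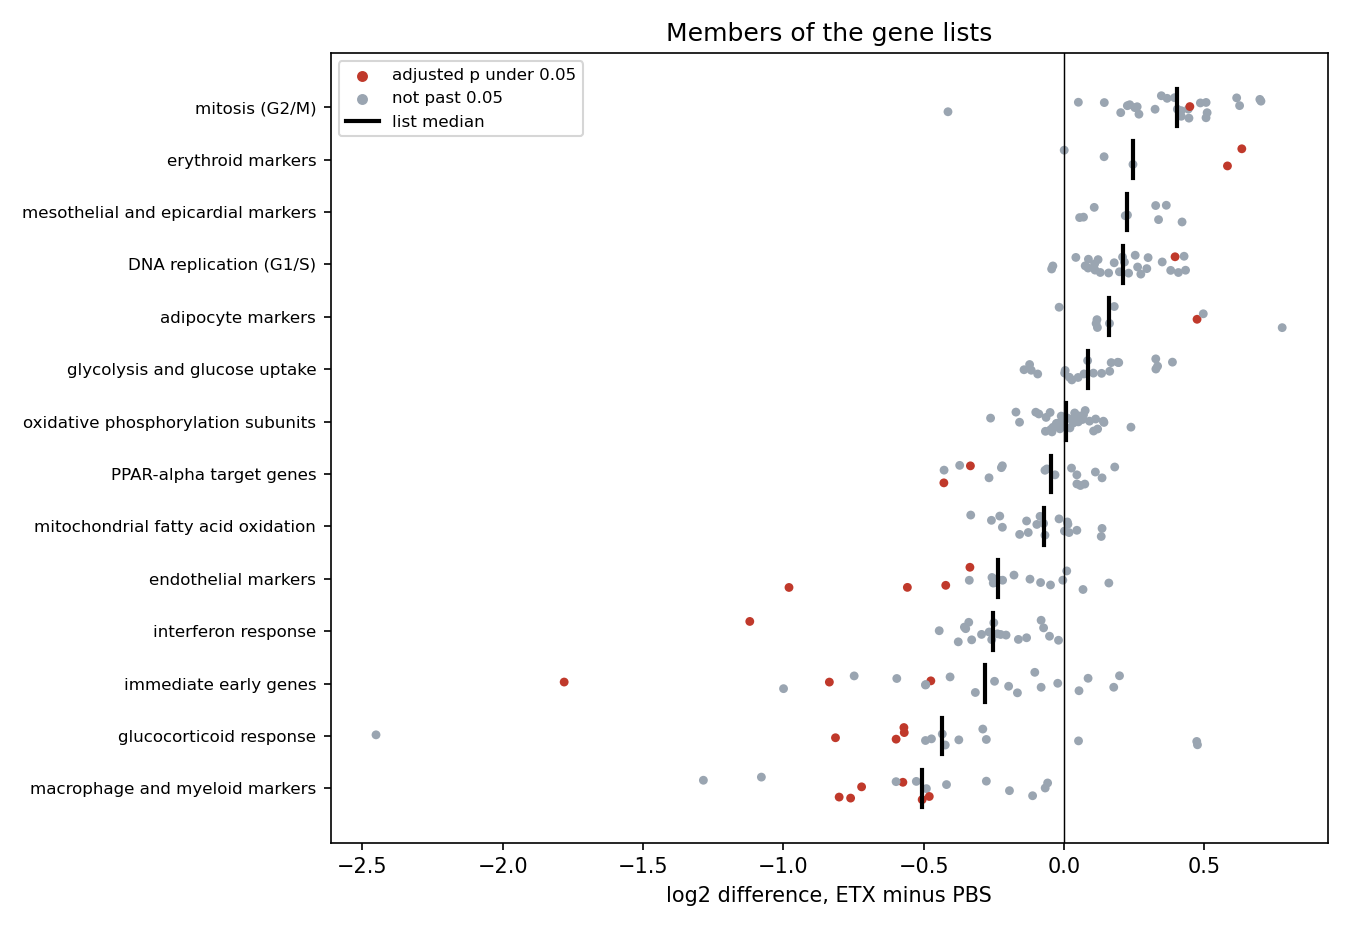
Log2 difference (ETX minus PBS, horizontal axis) of the members of 14 gene lists, with a point for each gene, red where its adjusted p is under 0.05, and a black bar for the list median. The medians run from 0.40 for mitosis to -0.51 for macrophage and myeloid markers, and the fatty acid oxidation list lies at -0.07.

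Macrophage and myeloid markers were lower in ETX: all 17 lay below 0, with a median of -0.51 (camera adjusted p = 7.5e-08, adjusted p = 0.465 with an estimated correlation). Over all genes 6 fell, and adjusted over the list alone 10 did. Csf1r, the receptor of macrophage colony-stimulating factor, fell from 7.88 ± 0.04 to 7.12 ± 0.09 (limma adjusted p = 0.0056), and the complement genes C1qc (1.49-fold lower, 0.00857), C1qb (1.42-fold, 0.0206) and C1qa (1.39-fold, 0.0227) fell as well. Csf1r and C1qc passed in all 6 fits without 1 heart, and C1qa and C1qb in 2 of them, with a limma adjusted p of up to 0.0921 and 0.0749. Endothelial markers were lower too (camera adjusted p = 0.000124, median -0.23, 16 of 19 below 0, adjusted p = 0.492 with an estimated correlation). The apelin receptor Aplnr (1.97-fold, limma adjusted p = 0.0116), Tie1 (1.47-fold, 0.0129), Esam (1.26-fold, 0.036) and the cadherin Cdh5 (1.34-fold, 0.0462) fell over all genes, and 11 members did adjusted over the list alone. Aplnr lost the call without PBS replicate 3 (limma adjusted p = 0.0514), Tie1 without PBS replicate 3 or ETX replicate 7 (up to 0.0604), and Esam and Cdh5 in at least 5 of the 6 fits. Lung transcripts were high in PBS replicates 3 and 9. Sftpc, the surfactant protein C of lung epithelium, was at 8.12 and 8.58 there, 3.59 in PBS replicate 12 and 3.10 to 3.31 in ETX. It did not pass (limma adjusted p = 0.122) but did without PBS replicate 12 (1.3e-05). The 9 lung markers passed as a list (camera adjusted p = 0.00561, median -1.67, adjusted p = 0.656 with an estimated correlation) with 0 called over all genes or adjusted over the list alone, and without PBS replicate 9 the list did not pass (median -0.65, adjusted p = 0.062). Without PBS replicate 12 its median was -2.70. In PBS replicate 12, without these transcripts, Csf1r was at 7.90, C1qa at 7.74 and Aplnr at 8.64, each above the 3 ETX hearts. Every called gene was without overlap between the groups, so this order follows from the call and says nothing on lung tissue.

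The glucocorticoid, immediate early and interferon lists were lower in ETX. In the glucocorticoid response list 12 of 15 members lay below 0 (camera adjusted p = 0.000526, median -0.43, adjusted p = 0.557 with an estimated correlation), and Nfkbia, the inhibitor of NF-kappa-B (1.76-fold), Errfi1 (1.51-fold), Tsc22d3 (1.48-fold) and Cebpd (1.48-fold) fell, with limma adjusted p between 0.0251 and 0.0496. Adjusted over the list alone 7 fell and 1 rose. Immediate early genes respond within minutes to stimuli and handling. In their list 16 of 20 lay below 0 (camera adjusted p = 0.00326, median -0.28, adjusted p = 0.559 with an estimated correlation). Nr4a1, Nr4a3 (1.79-fold, limma adjusted p = 0.0464) and Jun (1.39-fold, 0.0496) fell over all genes, and 7 did adjusted over the list alone. Without ETX replicate 10 the median of this list was -0.47, and without the 3 hearts with high atrial transcripts, which leaves ETX replicate 10 as the single ETX heart, it was -0.12 and the list did not pass (adjusted p = 0.439). With the atrial-marker score in the fit it was -0.24 (adjusted p = 0.00251), over a range of 1.9e-06 to 0.559 for all alternatives. All 20 interferon response genes lay below 0 (camera adjusted p = 0.000898, median -0.25, adjusted p = 0.647 with an estimated correlation), with the chemokine Cxcl9 called over all genes and adjusted over the list alone (2.17-fold, limma adjusted p = 0.0129). Cxcl9 passed in all 6 fits without 1 heart, and the other genes called here each lost the call in at least 4 of them. The interferon list had an adjusted p of 0.0911 without both PBS hearts with lung transcripts, where PBS replicate 12 is the single PBS heart, and did not pass with the lung-marker score in the fit of all 6 hearts either (median -0.19, adjusted p = 0.105). Its median was -0.16 without ETX replicate 6 and -0.40 without ETX replicate 10. With ETX replicate 10 as the single ETX heart, without the 3 hearts with high atrial transcripts, it was -0.019 and the direction of the test turned. With the atrial-marker score in the fit it was -0.23 (adjusted p = 0.00251), over a range of 3.0e-08 to 0.9 for all alternatives.

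Of the heart's own genes, the list of foetal and stress genes did not pass (camera adjusted p = 0.194, median 0.19), but did without PBS replicate 3 (adjusted p = 0.043). The list shares Nppa, Myl4, Myl7 and Mybphl with the atrial list, and PBS replicate 3 was the PBS heart with high atrial transcripts. That pass therefore cannot be told apart from atrial tissue. Acta1 and Fhl1 (1.38-fold, limma adjusted p = 0.0471) rose over all genes, and 6 rose and 1 fell adjusted over the list alone. The natriuretic peptide gene Nppa was 4.12-fold higher on average without passing (limma adjusted p = 0.14). Its log2 difference was 2.04 over all hearts, 3.0 without PBS replicate 3, where it passed (limma adjusted p = 0.00328), and 1.5 without PBS replicate 12. The list of atrial markers, which holds Nppa, passed without PBS replicate 3 as well. Nppa was at 11.89 to 12.48 in ETX, 12.05 in PBS replicate 3, and 9.28 and 9.04 in the other PBS hearts. Nppb (0.80, 0.106) and Tnni1 (0.87, 0.125) were not past the threshold either, and Tnni1 was lower at 0.48 without ETX replicate 6, where it passed (limma adjusted p = 0.0485). Myh7 differed by -0.11 (0.351), Myh6 by -0.10 (0.402) and Tnni3 by -0.23 (0.142). In the contraction and maturation list (camera adjusted p = 0.203, 0.0259 and lower in ETX without ETX replicate 6, 3 higher and 4 lower adjusted over the list alone) the potassium channel gene Kcnd2 fell 1.66-fold (limma adjusted p = 0.0251) and the sodium-calcium exchanger Slc8a1 rose 1.32-fold (0.0397). Atrial transcripts varied within both groups. Myl7 was at 8.46 in PBS replicate 3, 9.03 in ETX replicate 6 and 8.84 in ETX replicate 7, and at 5.89 to 6.24 in the other hearts. The atrial list did not pass (camera adjusted p = 0.38, median 0.49, 0 called either way), but passed without PBS replicate 3 (median 0.91, adjusted p = 0.00208) and without ETX replicate 10 (0.83, 0.0188). Its lowest median was 0.23, without ETX replicate 7. Acta1 passed in all 6 fits without 1 heart, Kcnd2 in 3, and Fhl1 and Slc8a1 in none.

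**Figure D3:**
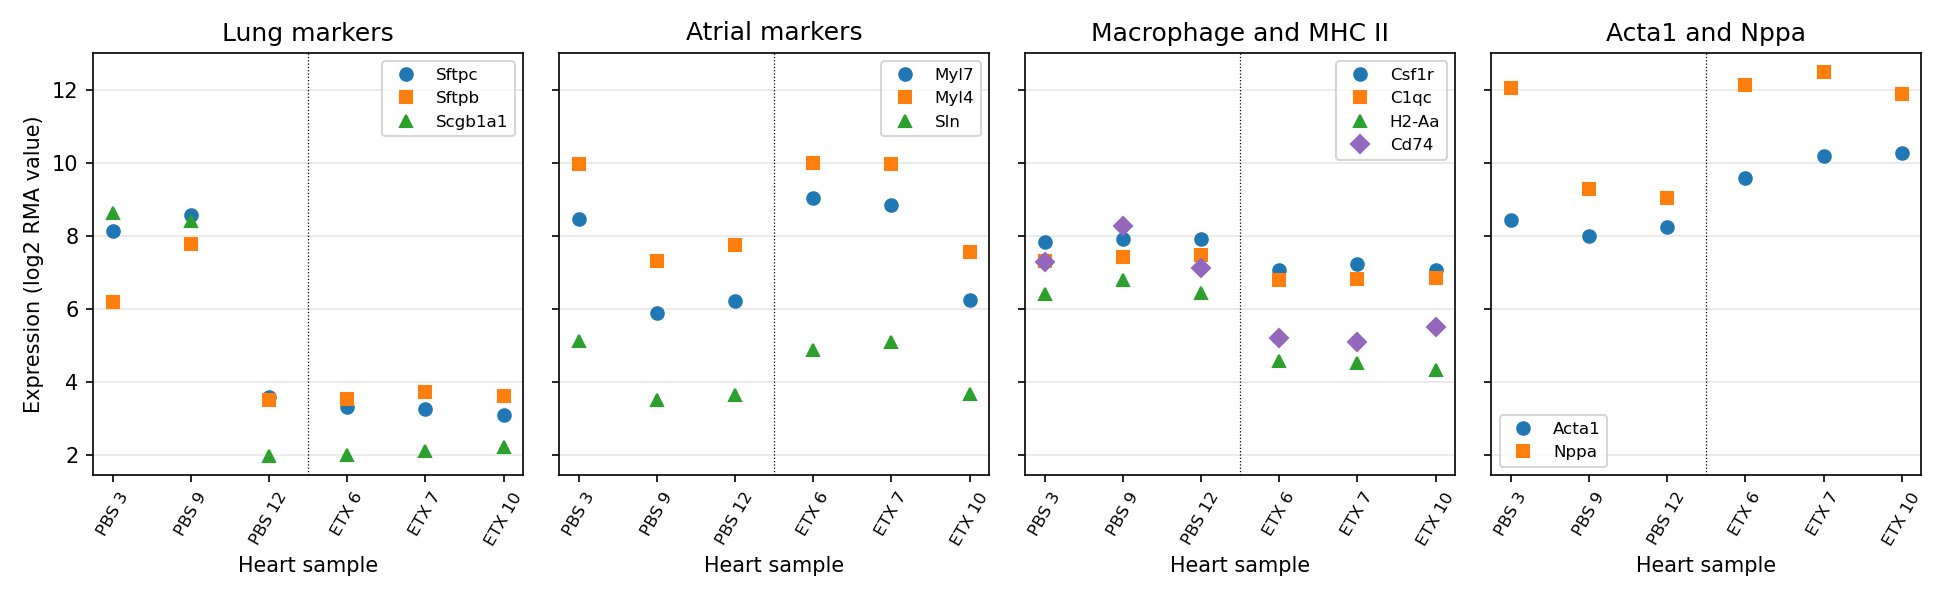
Log2 RMA value (vertical axis) in each of the 6 hearts (horizontal axis) for lung markers, atrial markers, macrophage and MHC class II genes, and Acta1 with Nppa. Sftpc is high in PBS replicates 3 and 9 (8.12 and 8.58), Myl7 in PBS replicate 3 and ETX replicates 6 and 7, and Csf1r and H2-Aa are lower in the 3 ETX hearts than in any PBS heart.

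Erythroid markers were higher (camera adjusted p = 0.0129, median 0.25, adjusted p = 0.492 with an estimated correlation), with Alas2 (log2 difference 0.58, limma adjusted p = 0.0348) and the anion exchanger Slc4a1 (1.55-fold, 0.0385) rising among 5 members over all genes and over the list alone. Mesothelial and epicardial markers (camera adjusted p = 0.0127, median 0.23, adjusted p = 0.56 with an estimated correlation) were higher with 0 of 9 called either way, and lost the call without PBS replicate 12 or ETX replicate 7 (adjusted p = 0.204 and 0.0554). Without PBS replicate 9 their median was 0.43, and with the lung-marker score in the fit it was 0.56. It was 0.58 without both hearts with lung transcripts and 0.079 without the 3 with high atrial transcripts, fits that leave 1 heart in a group. Adipocyte markers (camera adjusted p = 0.0129, median 0.16, adjusted p = 0.557 with an estimated correlation) were higher with Cidea as the called member of 9, and lost the call without PBS replicate 3 or ETX replicate 6 (adjusted p = 0.0753 and 0.0666, median 0.12 and 0.085). Ucp1 was at 5.72 in ETX replicate 6 and 3.57 to 3.77 elsewhere. The lists of extracellular matrix and fibroblast genes (camera adjusted p = 0.245), smooth muscle and pericytes (0.203), Schwann and neuronal cells (0.203), lymphocytes and thymus (0.838) and skeletal muscle (0.838) did not pass. Of their members Mmp2 (log2 difference -0.58, limma adjusted p = 0.0127), Pdgfra (1.42-fold, 0.0302), Gfra3 (1.45-fold, 0.0471), Cd4 (1.35-fold, 0.0468) and the calsequestrin Casq1 (2.12-fold, 0.0419) fell. Adjusted over each list alone, 2 rose and 7 fell of the matrix and fibroblast genes, 1 rose and 4 fell of the Schwann and neuronal markers, 1 fell each of the lymphocyte and skeletal muscle markers, and 0 of the smooth muscle list passed. The lists of inflammatory cytokines and chemokines (camera adjusted p = 0.203), p53 target genes (0.652), the integrated stress response (0.764), NRF2 antioxidant genes (0.838) and the circadian clock (0.953) did not pass. The cytokine list had a median of -0.68 and passed without PBS replicate 12 (-1.01, adjusted p = 0.000673). In the other fits without 1 heart it did not pass, with a median of up to -0.17. With the lung-marker score in the fit its median turned to 0.12 (camera adjusted p = 0.112). The list score was 5.68, 6.37 and 4.99 in PBS replicates 3, 9 and 12 and 5.10 to 5.40 in ETX. Adjusted over each list alone, 1 rose and 4 fell of the p53 list, 2 rose and 2 fell of the stress response list, and 0 passed in the others. Over all genes Mthfd2 (1.52-fold), Shmt2 (1.26-fold) and Perp (1.36-fold) rose, and Aldh1l2 (1.43-fold), Trp53inp1 (1.28-fold) and Sesn1 (1.25-fold) fell, with limma adjusted p between 0.0348 and 0.0496. Mmp2 lost the call without PBS replicate 3 (limma adjusted p = 0.0524), and each of the other genes called in these lists lost it in at least 4 of the 6 fits without 1 heart. The erythroid list did not pass with the lung-marker score in the fit of all 6 hearts (adjusted p = 0.0688), nor without both hearts with lung transcripts, where PBS replicate 12 is the single PBS heart (0.117). Its adjusted p over all alternatives ran from 0.00365 to 0.492.

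In transcript clusters outside the gene test, a run of 157 clusters with 59 distinct profiles was higher in ETX. This run was picked from clusters that passed and were higher in ETX, so its values are no independent test. Its mean was 2.63 to 2.66 in the PBS hearts and 4.07 to 4.35 in the ETX hearts, and 41 of the distinct profiles passed an adjusted p of 0.05 in limma. Distinct profiles can share probes. The annotation lists 3 genes together for 24 of these clusters and none for the others, so the signal cannot be given to a single gene.

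**Figure D4:**
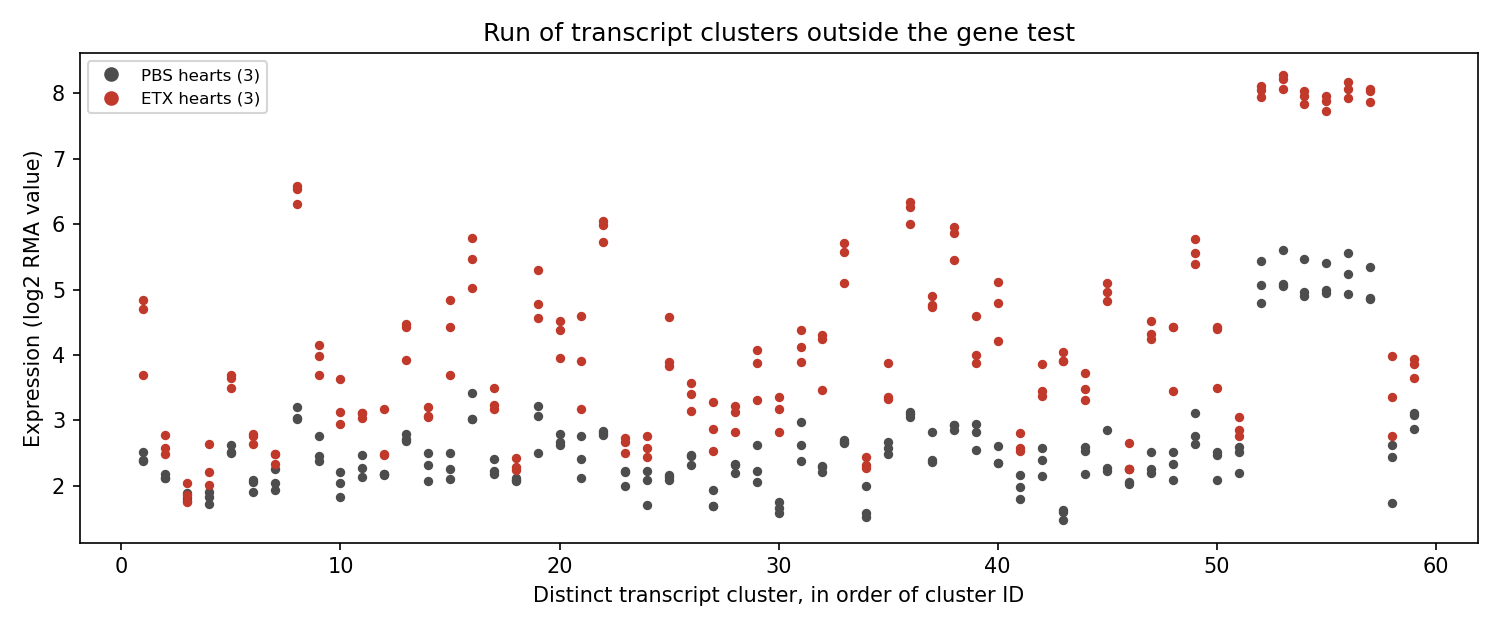
Log2 RMA value (vertical axis) of the 59 distinct profiles in this run, in order of cluster ID (horizontal axis), with a point for each of the 3 PBS and 3 ETX hearts. In 57 of the 59 profiles the points of the groups do not overlap.

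Of 34 lists 12 passed in camera with a preset correlation of 0.01, 6 higher and 6 lower, and fry, which tests each list by itself, passed 5, namely 4 of these 12 and the Schwann and neuronal markers (fry adjusted p = 0.0202). The 4 were the glycolysis, macrophage, endothelial and erythroid lists. Without the 3 hearts with high atrial transcripts, which leaves 1 ETX heart, 7 passed: the lung, mesothelial and adipocyte lists were lost too, and the endothelial list had a median of -0.12. With an estimated correlation 0 passed in camera, where 3 had an unadjusted p under 0.05. The count of 533 genes fell to 106, 241 and 192 without PBS replicates 3, 9 and 12, and to 160, 94 and 173 without ETX replicates 6, 7 and 10. It was 19 without both PBS hearts with lung transcripts and 2 without the 3 hearts with high atrial transcripts, fits that leave 1 heart in a group and assume that it varies like the others. It was 0 in a test without variance moderation, where 181 genes changed at least 1.5-fold at an unadjusted p under 0.05.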

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

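The tests on neural tissue, on repeated probes and on lung, atrial and skeletal muscle tissue and on other cell types were chosen after the results were seen; the test on other small nucleolar RNAs was written before its result. Signals appeared in transcript clusters that the gene test left out. In a fit of all 35556 clusters, 31 of the 1621 clusters with several genes (27 higher and 4 lower in ETX) and 141 of the 12146 clusters without a gene (126 higher and 15 lower) passed a limma adjusted p of 0.05, against 122 of the 21789 clusters with 1 gene. Of these, 24 clusters with several genes and 114 without a gene lay in a single run of cluster IDs from 10563897 to 10564209, and all 138 were higher in ETX. The run was picked as the largest group of nearby IDs among such clusters that passed and were higher in ETX. All clusters between its ends were then included.

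The run holds 157 clusters with 59 distinct value profiles (identical at 4 decimals), since many clusters repeat the same values. Its 24 clusters with several genes all list Snord116l2, Snord116l1 and Gm26504 together, so the signal cannot be given to a single gene; the rest carry no gene here. In ID order the run lies between Depdc1a and the shared cluster of Snurf and Snrpn. The mean of the distinct profiles was 2.66, 2.63 and 2.66 in PBS replicates 3, 9 and 12 and 4.25, 4.35 and 4.07 in ETX replicates 6, 7 and 10, a difference of 1.57 (95% interval 1.34 to 1.80), and 57 of the 59 profiles did not overlap between the groups. Because the run was picked for higher values in ETX, this difference, its interval and the count without overlap are no independent test. The largest difference was in cluster 10563913 (3.09 ± 0.10 in PBS, 6.48 ± 0.15 in ETX, SD, n = 3, limma adjusted p = 0.000121), and the brightest PBS level was in cluster 10564161, at 5.25 ± 0.30 against 8.19 ± 0.11 (7.65-fold, limma adjusted p = 0.000608). The PBS mean lies near the low end of the array, where a fold is not reliable.

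Repeated probes stay open for the number of clusters: 41 distinct profiles passed, all higher in ETX, but 10 pairs of profiles kept the same difference (to 4 decimals) in at least 2 hearts, so distinct profiles can share probes. A difference in how much small RNA the preparations kept would raise other small nucleolar RNAs, but the mean of 60 other such clusters differed by -0.050 (95% interval -0.18 to 0.08), with 0 of the 60 past the threshold. Neural tissue is argued against by 8 neural genes, which differed by 0.041 (95% interval -0.01 to 0.09). The neighbouring cluster of Snurf and Snrpn was 0.51 higher without passing (limma adjusted p = 0.0695), and Mkrn3 and Peg12 differed by -0.05 and -0.01. A change at this locus with treatment stays open and untested, as does a difference between litters or in parental genotype, which the labels do not give.

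The fall of macrophage and antigen presentation genes was weighed against lung tissue in PBS replicates 3 and 9. With the lung-marker score in the fit, the macrophage score differed by -0.34 (95% interval -0.78 to 0.10) against -0.53 without it, and since this interval holds 0, lung tissue and treatment cannot be told apart for the score with 6 hearts. The list still passed in camera at the preset correlation with the lung score (adjusted p = 1.1e-05), but its median shrank from -0.51 to -0.33. Its adjusted p over all alternatives ran from 9.1e-10 to 0.465. With the lung score Csf1r differed by -0.77, C1qc by -0.62 and C1qa by -0.60, against -0.76, -0.57 and -0.48 without it. These 3 genes are among the members with the smallest p and do not stand for the list. The score of MHC class II genes stayed lower at -0.67 (95% interval -0.88 to -0.47, against -0.84), which argues against lung tissue as the whole cause for its falling genes. That list was written after the data were examined, so its interval is no independent test of a fall. Without the lung score, Cd74, H2-Aa and H2-Ab1 carry most of it (-2.29, -2.07 and -1.51). H2-DMa, Ciita, H2-Oa and H2-Ob differed by -0.06, -0.11, -0.18 and -0.18. A lower share of every non-cardiomyocyte type would lower all their markers alike, but the macrophage score less the mean of 4 other cell type scores (matrix and fibroblast, endothelial, smooth muscle, mesothelial) differed by -0.51 (95% interval -0.85 to -0.16). The 4 scores did not move alike: the endothelial score differed by -0.23 (-0.33 to -0.12) and the mesothelial score by 0.24 (-0.30 to 0.77). The matrix and smooth muscle scores differed by -0.04 and -0.05. The macrophage score in this comparison was not adjusted for the lung score. A smaller or altered macrophage population in ETX hearts may be a candidate explanation; cell numbers were not measured.

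Acta1 and Nppa were weighed against atrial and skeletal muscle tissue. With the atrial-marker score in the fit, Acta1 stayed 1.79 higher in ETX (95% interval 1.32 to 2.27, against 1.80) and Nppa 1.76 higher (0.88 to 2.65, against 2.04). In this fit atrial tissue does not account for the whole of either, although Nppa does not pass over all genes. The limits are larger for Nppa. Among ETX hearts only replicate 10 had a low score of the atrial list (5.93, against 6.94 and 6.98). Nppa in PBS replicate 3, with high atrial transcripts, lay inside the ETX range. Bmp10 was high in that heart alone, so 1 score may not measure the same tissue in every heart. Skeletal muscle tissue would raise its markers, but their score differed by -0.10 (95% interval -0.17 to -0.02). This fall comes mostly from Casq1 (-1.08): 8 of the 12 markers lay above 0, by at most 0.14, and without Casq1 the score differed by -0.0062 (95% interval -0.11 to 0.10), which still argues against skeletal muscle as the source of a rise of 1.80. A change in cardiomyocytes themselves is a hypothesis and was not tested.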

How the results depend on the processing

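The fits without the hearts with lung or high atrial transcripts, those with a covariate and the added lists were chosen after seeing the data. The count of 533 genes stayed within 1.5 times under 5 alternatives (no filter, array weights, both normalizations, mean of clusters). It was 909 with genes under the median left out, 957 with trend and robust set and 1259 at an adjusted p of 0.1. It was 294 over all transcript clusters (188 higher and 106 lower, so that the majority turns, with 138 of the higher clusters in the run described above) and 0 in the unmoderated test. Leaving out 1 heart gave 94 (without ETX replicate 7) to 241, and fewer hearts raise the p-values by themselves. It was 19 without both hearts with lung transcripts, 2 without the 3 with high atrial transcripts, 120 with sex, 72 with the lung score and 301 with the atrial score as a covariate. The first of these leaves 1 PBS heart and the second 1 ETX heart, each assumed to vary like the others, and each covariate takes a degree of freedom. The count of 240 was 703 over all clusters, 746 at 1.3-fold and 55 at 2-fold, and 213 to 311 with 1 heart left out. The 12 lists became 0 with an estimated correlation, 5 with fry (4 of the 12 and the Schwann and neuronal markers), 7 with the single ETX heart left without the 3 with high atrial transcripts, and 11 to 14 with 1 heart left out. Lung markers turned to 0.13 without both hearts with lung transcripts and 0.19 with their score as a covariate, by construction. The interferon list had a median of -0.019 and turned in its test without the 3 hearts with high atrial transcripts, which leaves ETX replicate 10, the ETX heart with the highest score of this list. With the atrial-marker score as a covariate it was -0.23. Of the added lists, neutrophil genes turned to 0.42 without both hearts with lung transcripts and 0.67 with the lung score. Liver genes turned to -0.24 and -0.069 there and to -0.27 without the 3 hearts with high atrial transcripts. All 68 called named genes kept their sign under every alternative run. Their groups do not overlap, so leaving out hearts could not turn a sign, and this says little about stability. Of the 68, 20 passed in all 6 fits without 1 heart, and 20 passed with the lung score in the fit. The normalizations moved the median of all genes by 0.007 and -0.029. Of the 10 splits of the 6 hearts into 3 and 3, too few for a share under 0.05, the real split gave 533, 240 and 12, and the highest of the others 6, 69 and 10. Only 1 split, the real, gave counts as large. No paired analysis was possible because the groups share no replicate number.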

Other observations

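The 8 lists in this part were written after the data were examined, so their p-values and intervals are no independent test of a difference. The test on foetal growth genes was written before its result. Chaperones and folding enzymes of the endoplasmic reticulum were lower in ETX: 23 of 24 genes lay below 0, 11 fell over all genes and 17 adjusted over the list alone (camera adjusted p over the 8 lists = 1.6e-12, median -0.42, adjusted p = 0.0598 with an estimated correlation). The chaperone Hspa5 fell from 10.37 ± 0.05 to 9.65 ± 0.03 (SD, n = 3, limma adjusted p = 0.00487), Hsp90b1 from 10.21 ± 0.07 to 9.59 ± 0.02 (0.00649), Calr from 9.92 ± 0.03 to 9.35 ± 0.03 (0.00649) and Manf from 5.87 ± 0.02 to 5.34 ± 0.10 (0.014). The list score was -0.34 in ETX relative to PBS (95% interval -0.42 to -0.26). The list passed in all 6 fits without 1 heart, and with the lung-marker score in the fit its median shrank from -0.42 to -0.25. Of 10 MHC class II genes 5 fell over all genes and 6 adjusted over the list alone (median -0.62, camera adjusted p = 1.2e-07, adjusted p = 0.122 with an estimated correlation), with Ifi30 at -0.51 and H2-Eb1 at -0.73. Of 15 serine and one-carbon genes 13 lay above 0 (median 0.09, camera adjusted p = 0.0109, adjusted p = 0.28 with an estimated correlation), with Shmt2 and Mthfd2 rising and Aldh1l2 falling. The list did not pass without ETX replicate 10 (median 0.034). Of 25 ribosomal protein genes 20 lay above 0 (median 0.07, camera adjusted p = 0.00554, adjusted p = 0.454 with an estimated correlation) and 3 rose over all genes and over the list alone, and the list did not pass without ETX replicate 7 (median 0.021). The ribosomal median was 0.038 without PBS replicate 12 and 0.10 without ETX replicate 10.

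Platelet genes were higher in ETX (median 0.67, camera adjusted p = 3.0e-06, adjusted p = 0.382 with an estimated correlation) with 0 of 14 called over all genes and 5 over the list alone. Their score was 6.30 in ETX replicate 6, 5.30 and 5.43 in ETX replicates 7 and 10, and 4.94 to 5.04 in PBS, with Ppbp at 9.11 in ETX replicate 6. The list passed in all 6 fits without 1 heart, with a median of 0.30 without ETX replicate 6. Neutrophil and acute-phase genes were lower (median -0.94, camera adjusted p = 0.0109, adjusted p = 0.454 with an estimated correlation), with Saa3 at 10.35 in PBS replicate 9, 5.20 in PBS replicate 3 and 3.31 to 3.59 in the other hearts. Without PBS replicate 9 the list did not pass (median -0.24), and without PBS replicate 12 its median was -1.98. Liver plasma protein genes differed by a median of 0.61 (camera adjusted p = 0.011, adjusted p = 0.454 with an estimated correlation), with Alb between 4.32 and 9.10 across all 6 hearts. The list did not pass without PBS replicate 3, PBS replicate 9 or ETX replicate 6 (median 0.34, 0.39 and 0.31), and its median was 0.99 without PBS replicate 12 and 1.07 without ETX replicate 10. Bmp10, an atrial gene, was at 7.71 in PBS replicate 3 and 2.55 to 2.94 elsewhere. Xist was at 8.34 to 8.41 in PBS replicate 3 and ETX replicates 6 and 10 and at 2.61 to 2.87 in the other hearts, so each group held both sexes.

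The higher cell cycle genes may reflect a younger developmental state of the ETX hearts. Growth genes that fall after birth, such as Igf2, Dlk1 and Mest, would then be higher in ETX. The score of 12 such genes differed by 0.0059 (95% interval -0.05 to 0.06), against 0.29 for the cell cycle score. Their camera adjusted p in limma was 0.42. The upper end of the growth gene interval lies below the cell cycle difference of 0.29, which meets the bound set for this test. The cell cycle difference itself has a 95% interval of -0.05 to 0.63, which overlaps that of the growth genes. The explanation therefore stays open.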
